A study of Mus musculus with 2 samples.

How the data were processed

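The series measured acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation and sequencing in hearts of mouse embryos at day 11.5. The 2 samples are biological replicates of 1 group, each a pool of embryos of both sexes of strain B6NCrl. The labels give 109 embryos for replicate 1, and the number for replicate 2 is not given in the sources used here. They also give a size range of 300 to 500 with no unit. There is no second group, so the comparisons are between the replicates and between sets of genes within the peak lists.

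The authors deposited 4 peak lists in narrowPeak form on the mouse build mm10 (GRCm38), per the labels and the notes deposited with the samples. One list was called on each replicate, 1 on the pooled data, and 1 holds the replicated peaks. The aligner, the peak caller and their versions are not given in the sources used here. The labels name a possible control experiment, which was not used here. Each peak carries an enrichment, deposited by the authors as a ratio to a background that the sources used here do not name, a −log10 p-value and a −log10 q-value as the authors deposited them, and a deposited score that was not used for any result. The enrichment served to describe, rank or filter peaks within a list and, by rank, to correlate the replicates. The lists hold no read counts, so the depth of each library is unknown, and a deeper library can yield more and weaker peaks. The replicate 1 list holds 77925 peaks with −log10 p of 2.22 or more, and the replicate 2 list holds 100363 with −log10 p of 2.0047 or more. The lowest −log10 q was 0.549 in replicate 1, 0.339 in replicate 2 and 0.406 in the replicated list. The lists are thus not limited to peaks with a q-value under 0.05. All 52082 replicated peaks are also in the pooled list of 85758, and each carries the pooled enrichment. All 44169 pooled peaks that share at least 50% of either peak with a peak of both replicates are in the replicated list, which holds 7908 more on the chromosomes used, by a rule that the sources used here do not state. Of the replicated peaks, 3448 touched no replicate 1 peak and 4224 no replicate 2 peak, 160 of them neither. A replicated peak can therefore be absent from a replicate's own list.

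Gene positions came from the GENCODE vM21 basic annotation, a GRCm38 annotation, and sequence from the GRCm38.p6 reference. Every peak ended within the length of its chromosome in that reference. Peaks on chromosomes 1 to 19, X and Y were used, which left out 5 replicated peaks. The annotation gave 21851 protein-coding genes with 41438 TSSs. All 404 genes of the 23 lists were matched by symbol. A promoter peak overlapped the 1 kb either side of any TSS of a gene. A distal peak lay outside all such windows and went to the gene with the nearest TSS if its midpoint was within 100 kb. Unless another list is named, gene results refer to the replicated list, so a gene without a peak there can have one in a replicate. Domains joined distal peaks with gaps of up to 10 kb and were ranked by the sum over their peaks of length times enrichment. Coordinates are 1-based on mm10.

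A peak counted as shared when at least 50% of its length was covered by the other replicate's peaks, set against 100 random placements of the other replicate's peaks on the same chromosomes outside assembly gaps. Genes with a promoter peak or a domain were compared by Fisher's exact test, two-sided, and means of distal peaks by 100000 permutations of the list labels. Each list was also set against 10000 random gene lists matched in 10 bins on territory, the stretch of genome nearest to the gene, or on observed against expected CpG within 500 bp of the TSS. Motif strings were sought on both strands in distal peaks and in 1 region per peak of the same length and GC content (bins of 2 percentage points) outside all peaks, and 1345 of the 38573 distal peaks found no such region. Repeats were not masked, so peaks and background can differ in repeat content. Promoter peaks in 1 replicate only were tested per list by an exact binomial (McNemar) test at 77919 top-ranked peaks per replicate. Adjusted p-values are Benjamini-Hochberg, over the 23 lists or the 17 motif strings. Genes and peaks are not independent replicates, so these p-values describe how sets of genes differ within the peak lists and do not measure variation between embryos. Intervals on counts are 95% intervals and cover counting error only. The spread between replicates is given as SD over n = 2.

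The gene lists, the tests and the alternatives were fixed before the data were examined, except where the closing section says otherwise. So was the rule for named genes. It took per list the 2 members with the highest promoter enrichment, the 2 with the most distal peaks and, for heart lists, up to 2 without a promoter peak in alphabetical order. It also took the 12 top-ranked domains, the 10 promoter regions with the highest enrichment, and up to 5 list genes per direction with a promoter peak in 1 replicate only. Members without a peak beyond those 2, members of non-heart lists named with or without a peak beyond the rule, domain ranks of list genes and genes that a domain overlaps were named after their values were seen. Alternatives were a stricter peak threshold, the pooled list, each replicate alone, other overlaps, windows, TSS sets, distances and motif backgrounds, stratification by CpG content and, added later, lists without some members.

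The steps were tested on simulated data. With 60% of the replicate 1 peaks kept in place and the others moved at random, 60.3% of 77919 peaks were called shared. A simulated odds ratio of 5.90 for 286 list genes was recovered as 5.90, and a simulated 4-fold ratio of distal peaks in the same genes as 4.04. Of 200 random lists of 18 genes, 3.5% had an unadjusted exact p under 0.05 and 0 passed after adjustment. All 600 planted motif strings were found. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and samtools 1.23.1.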

Results

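H3K27ac peaks were mapped in pooled mouse embryonic hearts at day 11.5, when the looped tube is being partitioned into chambers and valves. The 2 biological replicates gave 77925 and 100363 peaks, covering 1.62% and 1.71% of the chromosomes. The authors' replicated list held 52082 peaks with a median length of 600 bp and a median enrichment of 4.77. Read depth is unknown, since the lists carry no counts. The series holds no other stage, tissue or treatment, and the questions addressed are how far the replicates share peaks and which genes and motifs the replicated peaks mark.

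The strongest regions were found in both pools of hearts and the weak ones often in 1 only. In the highest 10% by enrichment, 99.5% of the replicate 1 peaks and 99.8% of the replicate 2 peaks were covered by the other replicate's peaks, against 25.9% and 17.8% in the lowest 10%. Over all peaks, 42680 of 77919 in replicate 1 (54.8%, 95% exact interval 54.4 to 55.1) and 46863 of 100357 in replicate 2 (46.7%, 46.4 to 47.0) were shared. Random placement gave 1.67% and 1.7%, and none of the 100 placements reached the observed share (permutation p = 0.0099 for each replicate, the smallest that 100 placements can give). Peaks not shared had a median length of 249 bp and 224 bp, against 524 bp and 459 bp for shared ones. Across 44565 replicated regions with a peak in both lists, the replicates' enrichments had a Spearman rho of 0.737. Regions are not independent replicates, so no p is given.

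**Figure D1:**
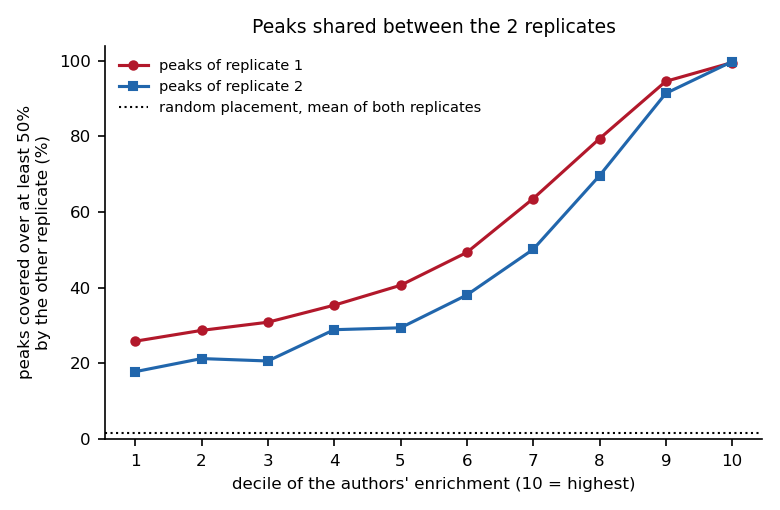
Share of each replicate's peaks covered over at least 50% by the other replicate's peaks (%), in 10 bins of the authors' enrichment within each list, with the random placement level dotted. Both curves start at 25.9% and 17.8% and reach 99.5% and 99.8% in the highest bin.

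H3K27ac lay at promoters far more often than random positions did. Of 52077 replicated peaks, 13504 (25.9%) overlapped the promoter of a protein-coding gene, 8.37 times the 3.10% of random placements. Introns held 42.0% of the peaks against 32.9% at random, exons 6.57% against 7.03%, and intergenic sequence 25.5% against 57%. Each replicate's own list had a lower promoter share, 21.4% in replicate 1 and 18% in replicate 2. None of the 10 promoter regions with the highest enrichment belonged to a gene of the heart lists. Rhof, a Rho family GTPase, led with an enrichment of 76.9 (chromosome 5, 123133536 to 123140688), before Arrdc3, an arrestin-domain gene, at 73.8 (chromosome 13, 80882460 to 80887222). Zc3h4 had 71.8, the transcription factor genes Sp3 and Klf7 66.7 and 62.1, and Pcbp1, which encodes an RNA-binding protein, 61.4. The chromatin genes Kmt5b and Kansl1 had 61.3 and 59.4, the kinase gene Dyrk1a 60.4 and Pcif1 59.2.

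Genes of the heart carried H3K27ac at their promoters, and genes of other tissues mostly did not. Of the 177 genes in the 10 heart lists, 162 (91.5%) had a replicated promoter peak, against 13 of the 109 genes (11.9%) in the 6 lists of other tissues and 11002 of all 21851 protein-coding genes (50.4%). In the replicates' own lists the shares were 94.1% ± 0.399 for heart genes and 16.5% ± 2.59 for genes of other tissues (SD, n = 2). The odds ratio was 79.8 (95% interval 36.4 to 175, Fisher's exact test, two-sided, p = 1.17e-44). It fell to 37.5 with peaks above the median enrichment alone and to 42.9 with the 5'-most TSS of each gene, and was 69.4 within strata of promoter CpG content. Of the heart lists, 9, all but the second heart field and outflow tract list, had more promoter peaks than other genes, with Fisher's exact p adjusted over the 23 lists between 6.86e-07 and 0.0438.

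All 25 cardiac transcription factor genes had a promoter peak in both replicates. Gata6, a zinc finger factor of early heart cells, had the highest enrichment in this list at 40.1, in a peak on chromosome 18 from 11047392 to 11058245 that also had 33.1 and 39.1 in replicates 1 and 2. Meis1, a homeobox factor, followed at 38.5 (chromosome 11, 19012168 to 19022002). In the sarcomere list 25 of 26 genes had a peak. Tnni1, the slow troponin I that the embryonic heart uses, had 40.4 and the tropomyosin gene Tpm1 had 34.0, while Obscn had a peak in replicate 1 alone, at 3.35. Of 25 genes of calcium handling and conduction, 21 had a peak, with Popdc2 at 31.9 and Gjc1, which encodes a connexin, at 30.9. The 4 without were Hcn1, Kcnj3, Kcnq1 and Sln.

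Most chamber genes were marked too. Of 13 atrial genes 11 had a peak, led by the atrial myosin light chain gene Myl4 at 29.7 (chromosome 11, 104576048 to 104579848) and the nuclear receptor gene Nr2f1 at 24.0, and Kcnj3 and Sln, a regulator of the calcium pump, lacked one. Of 13 ventricular genes 12 had a peak, led by the ventricular myosin light chain gene Myl2 at 24.6 (chromosome 5, 122099933 to 122108597) and Mpped2 at 19.9, and Kcne1 lacked one. With only the 5'-most TSS of each gene the atrial share was 61.5%, against 48.4% of all protein-coding genes. The list no longer passed the test (Fisher's exact adjusted p = 0.412), as Pitx2, Stard10 and Gja5 had their peak at another TSS.

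Most promoters of endocardial, cushion and epicardial genes were marked as well. Endocardial and endothelial genes had peaks at 23 of 24 promoters with a median enrichment of 7.07, against 22.2 for sarcomere and 8.64 for atrial genes, differences that were not tested. Egfl7 had 13.5 and Pecam1, a junction protein of endothelium, 11.9, and Nrg1 had no replicated peak although each replicate's own list held one, at 3.18 and 3.13. Cushion mesenchyme genes had peaks at 17 of 18 promoters, with Smad6, an inhibitor of BMP signalling, at 35.5 and the matrix gene Vcan at 14.3, and Postn had one in replicate 1 alone. In the epicardium list 10 of 12 genes had a peak with a median of 4.86. Tcf21 and Tbx18, transcription factors of the epicardium, had 14.6 and 11.5, and Aldh1a2 and Msln had none. With peaks above the median enrichment alone the epicardial share was 41.7%, below the 43.5% of other genes, and the cushion share was 66.7%, and neither call held. The epicardial call was also lost with the pooled list and with replicate 2 alone (Fisher's exact adjusted p = 0.052 and 0.0531).

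Of the 13 genes of the second heart field and outflow tract list, 9 had a promoter peak (69.2%, Fisher's exact adjusted p = 0.267 against other genes). Hand2 had 30.8 and the semaphorin receptor gene Nrp1 29.0. The 4 without were Fgf8 and Fgf10, growth factors of the progenitor field, and the progenitor factors Tbx1 and Six1. Cardiac signalling genes had peaks at 25 of 27 promoters, with the BMP and TGF-beta inhibitor Smad7 at 47.3 and the Notch target Hes1 at 40.0014. Heyl and Nrg1 had none in the replicated list, although replicate 2 held one at Heyl (3.89) and each replicate one at Nrg1.

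None of the 26 neural genes had a replicated promoter peak (Fisher's exact adjusted p = 2.81e-07), although 3 had one in replicate 2 alone. The lists of foregut and lung endoderm, limb and distal Hox, and pluripotency and germ line had 1 of 16 each (Fisher's exact adjusted p = 0.000481 for each), namely Krt18 at 3.85, Sall1 at 17.7 and Dazl at 7.20. In the liver list 5 of 19 genes had a peak, with Prox1, a homeobox factor also used in heart and lymphatic endothelium, at 17.2 and Nr0b2 at 9.53, and Alb, Afp and Ttr had none (Fisher's exact adjusted p = 0.0438, a call lost with the 5'-most TSS or with peaks above the median enrichment alone). Random lists matched on promoter CpG content had 23.1% (95% between 5.26% and 42.1%), so the liver share of 26.3% was not low for such promoters. In the skeletal muscle list 5 of 16 had one, led by Mylpf at 15.2 and Ckm at 8.72, without the determination factors Myod1, Myf5 and Myog, and this list did not pass the test (Fisher's exact adjusted p = 0.147).

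Most erythroid promoters were marked, and few of leukocyte or neural crest genes. Of 18 erythroid genes 15 had a promoter peak (Fisher's exact adjusted p = 0.0108), with the transferrin receptor gene Tfrc at 15.5, Ank1 at 10.8 and the embryonic globin gene Hbb-y at 7.92. Macrophage and leukocyte genes had 3 of 15, namely Cd68 at 4.09, Runx1 at 3.74 and Laptm5 at 2.65. Neural crest and glia genes had 2 of 12, Mpz at 9.07 and Ednrb at 7.92. Both shares lay below that of other genes (Fisher's exact adjusted p = 0.0272 for each), a call that the neural crest list lost in 4 of 6 alternative settings and the leukocyte list with replicate 2 alone. Against lists matched on promoter CpG content the leukocyte share of 20% was not low (mean 22.2%, 95% between 6.67% and 40%), while the neural crest share of 16.7% was (53.9%, 33.3% to 75%). Promoters of general genes were marked, at 22 of 22 housekeeping, 17 of 17 glycolysis, 19 of 20 cell cycle and 15 of 17 fatty acid oxidation genes. Actb had 41.8 and Ywhaz 40.5, the glycolytic enzyme gene Eno1 35.5 and the glucose transporter gene Slc2a1 32.3, Ccnd1 22.9 and Aurkb 16.3, and the coactivator gene Ppargc1a 16.7 and Etfa 14.6.

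**Figure D2:**
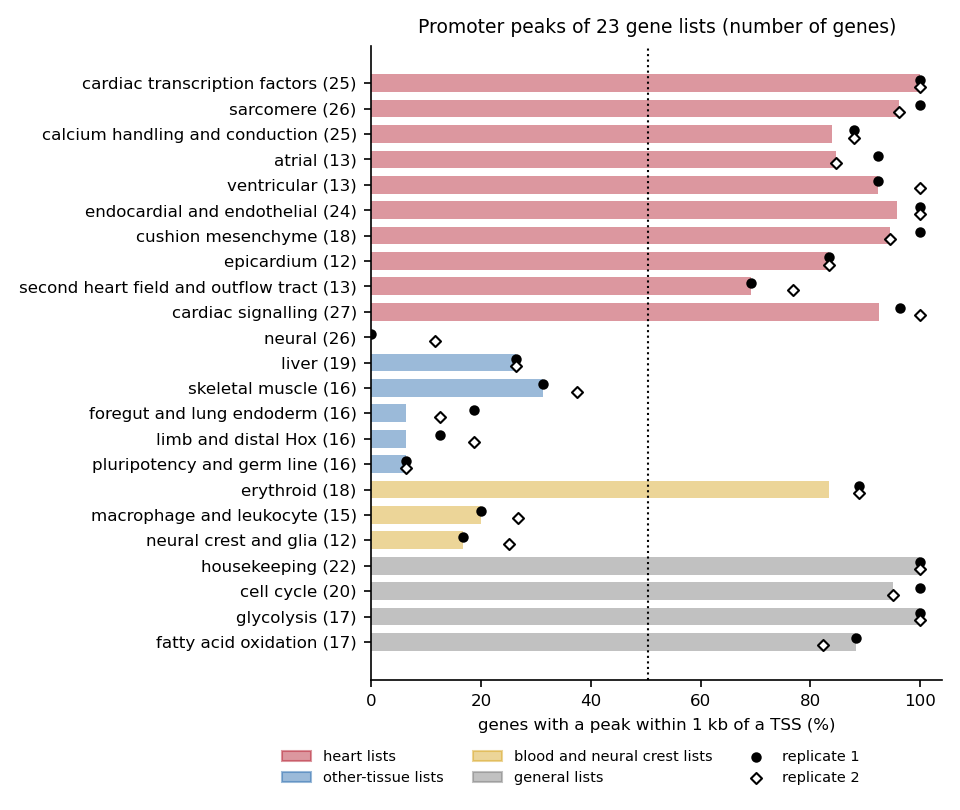
Genes with a peak within 1 kb of a TSS (%) in each of 23 gene lists, with bars for the replicated list, points for each replicate's own list and the dotted line at the 50.4% of all protein-coding genes. Heart lists lie between 69.2% and 100%, lists of other tissues between 0% and 31.2%.

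Heart genes were also surrounded by more distal peaks, the class that holds enhancers. Heart-list genes had 7.99 ± 8.79 distal replicated peaks per gene (SD over 177 genes), against 0.991 ± 2.33 for the 109 genes of other tissues, an 8.06-fold difference (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). This ratio is not adjusted for territory, on which only the random lists below were matched. The replicates' own lists gave means of 12.7 and 15.8 for heart genes and 1.5 and 2.12 for genes of other tissues. Cardiac transcription factor genes had 15.2 each, against 3.11 in random lists matched on territory, with 47 at Tead1 and 34 at Meis1. Calcium handling and conduction genes had 9.60, with 41 at the calcium channel gene Cacna1c and 27 at the calcium release channel gene Ryr2. Sarcomere genes had 6.04, with 18 at Tpm1 and 15 at Actn2, and ventricular genes 8.23, with 25 at Lbh and 13 at Mpped2.

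Signalling genes had 9.67 distal peaks each, with 59 at Smad6 and 29 at Smad7, cushion genes 7.28, with 59 at Smad6, which is in both lists, and 13 at Snai1, and endothelial genes 7.38, with 24 at Nfatc1, a factor of valve endocardium, and 21 at Ets1. These 7 heart lists lay above the range that held 95% of matched random lists. Without Smad6 the cushion mean was 4.24, within a range of 0.941 to 6.06, so that call rests on Smad6. The other 6 lists stayed above the range without their member with the most distal peaks, although matched lists kept theirs. The 3 remaining heart lists lay within their ranges. Atrial genes had 4.08 with 9 each at Myl4 and Nr2f2, second heart field genes 4.77 with 16 at Nrp1 and 14 at Mef2c, and epicardial genes 2.08 with 7 at Tcf21 and 5 at Wt1, against 2.06 in matched lists. With peaks above the median enrichment alone epicardial genes had 0.417, below the 0.869 of matched lists. Neural genes, at 0.577, lay below the matched range, with at most 5 at Rbfox3 and 4 at Neurod1. The remaining lists of other tissues lay within it. Liver genes had 1.95, with 15 at Prox1 and 12 at Apoa1, endoderm genes 1.25, with 9 at Sftpb and 2 at Foxj1, and skeletal muscle genes 1.06, with 7 at Tnnt3 and 3 at Chrna1. Pluripotency and germ line genes had 0.688, with 7 at Nanos3 and 2 at Utf1, and limb genes 0.5, with 4 at Sall1 and 2 at Tbx4. Without Nanos3 the germ line mean was 0.267, below a range of 0.333 to 3.47, but the matched lists kept their top members, which favours a low value.

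Erythroid genes had 3.39 each, above the matched range of 0.167 to 2.5, with 11 at Hbb-y and 10 at Ank1, and glycolysis genes 4.94, with 30 at Slc2a1 and 12 at Hk2. Housekeeping genes had 2.95, also above matched lists, with 16 at Eef1a1 and 10 at Ywhaz. Cell cycle genes had 1.7, with 7 at Mki67 and 6 at Ccnd1, and fatty acid oxidation genes 2.71, with 19 at Ppargc1a and 5 at Cd36, and both lay within the range. Leukocyte genes had 0.667, with 5 at Laptm5 and 2 at Runx1, and neural crest genes 1.25, with 9 at Ednrb and 2 at Erbb3, also within it. Peaks were given to the nearest TSS, which need not be the gene they act on.

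**Figure D3:**
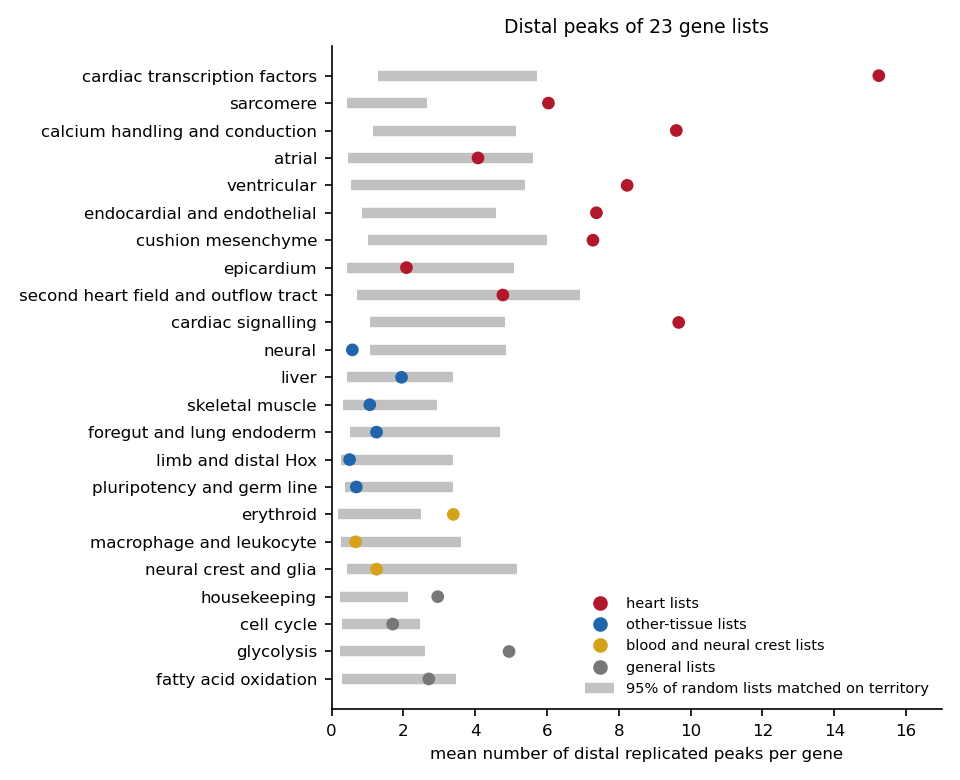
Mean number of distal replicated peaks per gene for 23 gene lists (points), with grey bars for the range of 95% of random lists matched on territory. Cardiac transcription factor genes lie at 15.2 and neural genes at 0.577.

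The highest-ranked clusters of distal peaks lay near Unc5b, Actn4 and Il17b, and heart genes were often nearest to a cluster of the top 500. The 500 top-ranked domains of 16794 held 14.4% of the distal peaks in a median length of 28.6 kb, against 1.10 kb for the others. The highest-ranked was a domain of 58.4 kb and 23 peaks over Unc5b, a netrin receptor gene (chromosome 10, 60771679 to 60830076). Next came 65.7 kb over Actn4 and Capn12 (chromosome 7, 28892844 to 28958592) and 53.6 kb nearest to Il17b (chromosome 18, 61631319 to 61684936), which overlaps the non-coding genes Carmn and Bvht and the smooth muscle microRNA genes Mir143 and Mir145a. Ranks 4 to 6 lay over Mical2, a regulator of actin, Ddc and Igf2r, the last over the imprinted non-coding gene Airn.

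The domain nearest to Cstad, at rank 7, overlapped no protein-coding gene. Rank 8, nearest to Mrpl23, overlapped H19 and Tnnt3 (chromosome 7, 142506213 to 142590935), and rank 9, nearest to Scyl1, overlapped Malat1 and Neat1 (chromosome 19, 5786693 to 5852816). Ranks 10 to 12 lay over the RNA-binding protein genes Msi2 and Rbpms and over Ahdc1. Of the 177 heart genes, 38 (21.5%) were nearest to a top-ranked domain, against 1 of 109 genes of other tissues, Nanos3 (odds ratio 29.5, 95% interval 3.99 to 218, Fisher's exact test, two-sided, p = 5.59e-08). Over all protein-coding genes the share was 2.07% (453 genes). The domain tests were not matched on territory, and a domain went to its nearest TSS at any distance. The odds ratio was 14.6 with the pooled list, where 2 genes of other tissues were nearest to one. Among cardiac transcription factor genes 13 of 25 were, with Gata4 at rank 19, Hand2 at 34 and Nkx2-5, the homeobox factor of heart precursors, at 40. Among sarcomere genes 8 of 26 were, with Actn2 at rank 50, and no atrial or epicardial gene was. Calcium handling (6 of 25), ventricular (3 of 13), endothelial (5 of 24), signalling (5 of 27) and glycolysis genes (3 of 17) also passed the test against other genes (Fisher's exact adjusted p between 7.46e-05 and 0.0159), and cushion (2 of 18), second heart field (1 of 13) and erythroid genes (1 of 18) did not. The ventricular call was lost with the 2 kb window, the 5'-most TSS (1 of 13 each) and joining within 5 kb (2 of 13), and the glycolysis call with the 5'-most TSS and with peaks above the median enrichment alone (2 of 17 each). Smad6 held the highest-ranked domain of any heart gene, at rank 13, with 27 distal peaks in 81.5 kb (chromosome 9, 64013426 to 64094963).

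**Figure D4:**
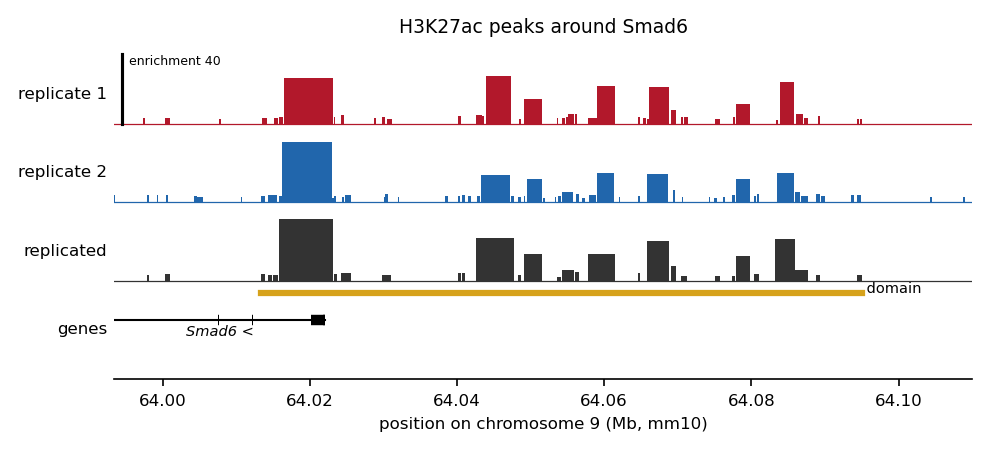
Peaks of both replicates and of the replicated list on chromosome 9 from 63993427 to 64109963 (mm10), with height as the authors' enrichment, the domain as a bar and the exons of Smad6 as boxes. Within the domain replicate 1 has 39 peaks, replicate 2 has 48 and the replicated list 28, promoter peak included, and the highest replicated enrichment is 35.5.

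Of the 17 motif strings, that of MEF2, a muscle enhancer factor, was the most enriched in distal peaks. A MEF2 string was present in 3.45% of 37228 distal peaks against 0.741% of background regions of the same length and GC content (odds ratio 4.79, 95% interval 4.20 to 5.46, Fisher's exact test, two-sided, adjusted p = 1.47e-157). Strings of TEAD (36.9% against 31.0%, odds ratio 1.30), GATA (46.3% against 40.1%, 1.29), ETS (1.32), MEIS (1.23), NKX2 (1.21) and SOX factors (1.17) were enriched as well. Both E-boxes listed for HAND and TWIST factors were depleted, at odds ratios of 0.669 (CATATG) and 0.937 (CATCTG), as was the T-box string at 0.885, and the SRF string did not differ (1.06, Fisher's exact adjusted p = 0.143). Of 6 control strings, the E-box CAGCTG, listed as neural but also bound by muscle E-box factors, was enriched at 1.32. The CTCF string was depleted at 0.479, with OCT at 0.868 and REST at 0.93, and HNF4 and HNF1 did not differ. HNF4 was enriched in the pooled list (1.16, Fisher's exact adjusted p = 0.0296). The REST depletion was lost at the summit, against the flanks and with replicate 2 alone, and that of the T-box string at the summit.

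The background mattered for some strings. Against flanks 5 kb from each peak, which were lower in GC (45% against 49.1%), GATA was depleted (0.967, Fisher's exact adjusted p = 0.0457). The NKX2 and SOX enrichments and the CATCTG depletion (1.01) were lost, while MEF2 (2.96), TEAD (1.25), MEIS (1.34) and ETS (1.91) stayed enriched. The control E-box CAGCTG stayed enriched too, at 1.7, above TEAD and MEIS and below MEF2 and ETS. Enrichment against the flanks was thus not limited to strings of heart factors. The SRF string was enriched against the flanks (1.16), in peaks above the median enrichment (1.26) and in each replicate's own list, and ETS was not in the 200 bp at the summit (1.10, Fisher's exact adjusted p = 0.441).

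**Figure D5:**
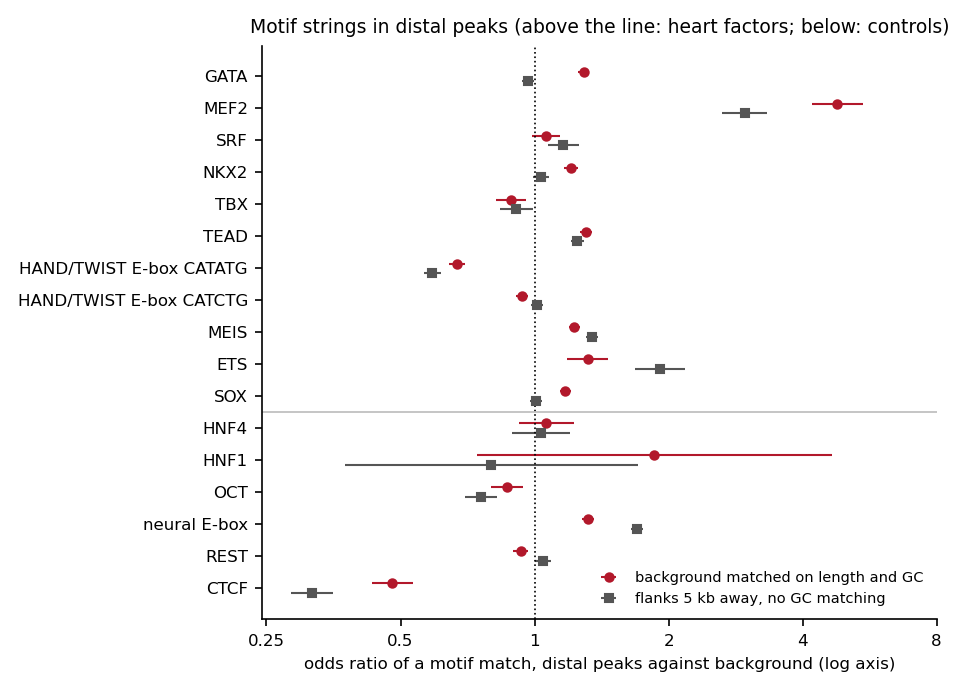
Odds ratios (log axis) with 95% intervals for a match to 17 motif strings in distal peaks, against regions matched on length and GC (circles) and against flanks 5 kb away (squares). MEF2 is highest at 4.79 and CTCF lowest at 0.479 with the matched background, and GATA falls from 1.29 to 0.967 with the flanks.

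No list of genes separated the replicates. With 77919 top-ranked peaks in each, 17 list genes had a promoter peak in replicate 1 only and 9 in replicate 2 only. The former were led by the erythroid gene Rhag at 5.17, Actn3 at 4.94, Cd36 at 4.59, Grhl2 at 4.23 and Kcnj2 at 4.17, the latter by Erbb3 at 5.38, Chrna1 at 4.32, Laptm5 at 4.15, Hba-a2 at 4.02 and Heyl at 3.89. Of the 23 lists, 0 differed by the exact McNemar test at an adjusted or an unadjusted p under 0.05. Over all genes, 797 had a peak in replicate 1 only and 571 in replicate 2 only (binomial exact p = 1.08e-09, two-sided), and with all peaks of each list the direction turned, to 571 and 815. No list had more than 3 such genes, and the exact test needs 6, so differences of a few genes per list could not be detected.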

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

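No test in this part was chosen after its result was seen, since the values below were not tested, and no technical or biological explanation of them was tested. The replicated list holds 5 peaks on sequences outside chromosomes 1 to 19, X and Y, of 52082, and the pooled list and the replicates' lists hold 7, 6 and 6. They are singled out because that is a signal in data left out of every comparison.

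The pooled list holds 6570 peaks that are outside the replicated list and touch no peak of either replicate. They are singled out because no comparison used them alone. They had a median enrichment of 2.89, at most 4.77, a median length of 208 bp, and 7.49% lay at promoters, against 25.9% of the replicated peaks.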

How the results depend on the processing

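The erythroid list without Tfrc, Epor and Ank1, and each list without its member with the most distal peaks, were alternatives chosen after the data were seen. Of 657 alternative values, 47 belong to the results that answer a comparison. Of these, 46 kept their direction and their side of the threshold, or for untested values stayed within their interval. For the count of enriched heart strings the criterion was a factor of 1.5 (5 to 8 against 7), and for the count of lists that differ between replicates it was 0. That last count could not leave 0, since no list reached the 6 genes with a peak in 1 replicate only that the exact test needs. The shares of shared peaks and of peaks at promoters were tested against random placement only. Across settings they were at least 31.6% and 17.96%, against at most 4.4% and 5.37% in any placement. Their calls could thus hardly change, and their being kept says little about how far they depend on the processing. The count of strings hides changed members, as GATA, NKX2 and SOX lost their enrichment against the flanks while SRF gained one. The odds ratio for promoter peaks of heart against other tissues ranged from 37.5 to 105, the ratio of distal peaks from 6.69 to 8.41, the share of heart genes nearest to a top-ranked domain from 16.4% to 30.5%, and the shared peaks of replicate 1 from 40.7% to 67.2%. The value that did not hold was the rank correlation of the replicates, which moved from 0.737 to 0.756 with the −log10 p in place of the enrichment, beyond its interval of 0.733 to 0.742. That interval treats 44565 regions as independent, which they are not, so it is too narrow to judge the move by. The cause of the move was not tested.

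Of 610 values for single lists and motifs, 554 kept call and direction, 23 lost a call, 6 gained one and 27 reversed. With peaks above the median enrichment alone, epicardial genes had promoter peaks in 41.7% and 0.417 distal peaks each, skeletal muscle genes 0.625 distal peaks each, and HNF4 an odds ratio of 0.996. With the 2 kb window epicardial genes had 1.92 distal peaks, below the mean of matched lists. With flanks as background GATA had an odds ratio of 0.967, the E-box CATCTG 1.01, REST 1.04 and HNF1 0.79993, and at the summit SRF had 0.964 and HNF1 an odds ratio of 0. Without replicate 1 or 2, HNF1 ranged from 0.818 to 1.78 and HNF4 from 0.955 to 1.0988. Without the member with the most distal peaks, epicardial genes had 1.64 and liver genes 1.22. Both were below the mean of matched lists, which kept their top members (1.97 and 1.38), but well within the matched ranges (0.273 to 5.09 and 0.333 to 3.06).

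Lists with no gene nearest to a top-ranked domain turned wherever 1 was. Atrial genes had 15.4% with the 5'-most TSS and 0% to 7.69% without replicate 1 or 2. Housekeeping genes had 4.55% with the 5'-most TSS, joining within 5 kb, the pooled list, the 2 kb window or peaks above the median enrichment, 13.6% with the top 1000 domains, and 9.09% without replicate 1 or 2. Liver genes had 5.26% with the pooled list or the top 1000 domains. The cause was not tested. The flanks were not matched on GC content and had a lower one (45% against 49.1%), and whether that moved the motif values was not tested. Depth is unknown, so what it limits could not be measured.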

Other observations

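The tests of blood cells, of weak peaks and of the borders of replicate 2 peaks below, the length bins used for non-coding genes, and the genes named in the next paragraph were chosen only after the results were seen. Several genes outside the lists had more distal peaks than most heart genes.

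Genome-wide the most distal replicated peaks were at Zmiz1, which encodes a transcriptional coregulator, with 62 in a territory of 200.043 kb. Smad6 had 59, Mical2 58, Foxp1 54, Dab2ip 53, and Rbpms and Tns1 52 each. Rbfox2, a splicing factor gene, Rere and Tead1 had 47 each, Cacna1c 41 and the chromatin remodeller gene Chd7 40. Chromosome X held 826 replicated peaks (1.59%) and Y held 2. Genes with a promoter peak had their longest such peak at a mean of 4.68 ± 2.91 kb in the sarcomere list (SD, n = 25 genes), 3.02 ± 2.19 kb in calcium handling (n = 21) and 0.907 ± 0.544 kb in epicardium (n = 10).

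Erythroid genes carried promoter peaks at 83.3% of 18 genes, above the upper bound of 38.9% in random lists matched on promoter CpG content, which argues against a base rate of such promoters. Neighbouring promoters are argued against too, since 0% of the 15 marked genes shared every promoter peak with a gene outside the list. Distal peaks, at 3.39 per gene against an upper bound of 2.5 in matched lists, would go with blood cells in the dissected hearts. They do not single out blood cells, since housekeeping (2.95) and glycolysis genes (4.94) also lay above their matched ranges. Peaks at the globin genes Hbb-y (7.92), Hbb-bh1 (6.72), Hba-x (6.14) and Hba-a1 (4.57) would go with blood cells too. The globin genes Hba-a2 and Hbb-bt and the gene Rhag had no replicated promoter peak. Replicate 1 alone held one at Rhag (5.17), replicate 2 alone one at Hba-a2 (4.02), and the pooled list one at each of Hba-a2 and Hbb-bt. Without Tfrc, Epor and Ank1, which other cells also use, 12 of 15 genes had a peak (Fisher's exact p = 0.0352, two-sided), with 3.13 distal peaks each, and no member stands in another list. No sort or gate is named in the labels, and no biological alternative was tested.

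Why peaks were not shared between replicates stays open. That 99.5% of the highest 10% of replicate 1 peaks by enrichment were covered by replicate 2 is the observation itself, so it does not test whether the others are weak peaks near the calling threshold. Different borders of the same regions are argued against for most unshared replicate 2 peaks, since 84.1% touched no replicate 1 peak. The share that touched one was 15.9%, under a bound of 25% chosen after the value was seen, so the bound adds no support. For replicate 1 the share was 25.7%, between the bounds of 25% and 50% set beforehand, which left borders open there for part of the peaks, as 74.3% touched none. Different tissue content of the pools was not excluded. At most 3 genes of a list had a promoter peak in 1 replicate only, but the exact test needs 6, so the bound of 5 set beforehand was too low to exclude a difference.

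Top-ranked domains held promoters of long non-coding RNAs more often than lower-ranked domains of like length, but the ranking itself can produce this. Distal peaks lay away from protein-coding TSSs only, so peaks at non-coding promoters added to the rank score. The draws were not matched on enrichment, so the test cannot separate such promoters from the ranking. A TSS of a long non-coding RNA lay in 24.75% of 400 top-ranked domains, against an upper bound of 21.25% in lower-ranked domains matched on length. Over all 500 the values were 27.8% and 19.4%, but the smallest pool of lower-ranked domains in a length bin was 2, so the bins were restricted to those with at least 20. Carmn, H19, Malat1, Neat1 and Airn, named above, overlap such domains.

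Heart transcription factor genes may have broader promoter peaks than housekeeping genes. Their longest promoter peak had a mean length of 5.69 ± 3.47 kb (SD, n = 25 genes) against 2.11 ± 1.46 kb (n = 22), a difference of 3.57 kb (permutation p = 5e-05, two-sided). The longest peak was taken over all TSSs of a gene, and the 2 lists were not matched on the number of TSSs. Expression was not measured here, so whether length follows the level of expression stays open.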
